A study of Mus musculus with 7 samples.

How the data were processed

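Glomerular RNA of 7 mice was measured by RNA sequencing, 1 library per animal (3 knockdown, 4 control), the design text counting animals. Glomeruli were isolated after bead perfusion with a magnet and sieving, per the labels' protocols. Libraries were made from poly-A RNA with an Illumina mRNA kit and ribosomal RNA depletion, per the labels. Reads were aligned with BWA and the genome build was mm10, per the submitters' processing notes. The BWA version, the counting method, the use of strand and the normalization are not given in the sources used here.

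The authors deposited 1 table per library with a gene symbol and a value on a log scale, read here as log2, for the same 12958 symbols. The base is not stated; the antilogarithms to base 2 summed to nearly equal totals in all libraries, and values ran from 2.32 to 17.2. If the base were another, fold changes would be scaled by a constant and tests would not change. Without counts, neither depth nor counting error could be given, and tests built for counts were not used. Symbols were matched to GENCODE mouse release M21, on GRCm38, the same build as mm10, which held 12701 of them, and coordinates are 1-based. The tables held 18 symbols that a spreadsheet had turned into dates, none past the threshold.

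The values bore marks of earlier processing. In the libraries titled G, 108 genes differed between libraries only by the same library offsets (within 0.003), with means from 3.55 to 6.41, as a fixed fill-in value would leave. With shuffled offsets the highest number in 20 shuffles was 0. These genes, which include the list members Ltbp1, Meis2, Rpl29 and Tcf7l2, stayed in the tests, and 0 of them passed. The deviations of knockdown replicate 3 and control replicate 4, the CB6 pair, from their group means had a correlation of -0.958 across genes, which are not independent replicates. A fit of the groups alone then counts 5 residual degrees of freedom where the fit with title style has 4, so that p-values of the group fit are too small if the values were adjusted for a batch before deposit. Counts from both fits are given for this reason.

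Knockdown was compared with control by limma 3.58.1 in R 4.3.3 with an intensity trend, on the log2 values as deposited, with Benjamini-Hochberg adjustment and a threshold of 0.05. A filter requiring a value above the table minimum in at least 3 libraries removed 0 genes. Gene lists of at least 3 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists. None of the mitochondrially encoded genes of a further list was measured. Two-sided exact permutation tests used all 35 splits of the libraries, and Fisher's exact tests were run per chromosome. The bootstrap intervals of list medians used 10000 resamples of genes and do not cover the spread between animals.

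The genes named are Shroom3, the 15 higher and 15 lower genes with the smallest p among those past the threshold, up to 4 members of each list past it with the smallest p or, where none passed, the 2 with the highest mean, and Fyn and Nphs1. Results of 1 list and 1 further gene that this rule names are not reported here. This rule, the lists, the tests and the alternatives were fixed before the data were examined, except where stated. The exact permutation test was planned for Shroom3 alone. Those of Fyn, Nphs1, list means and differences between marker lists, and the look at genes near Muc13, were not in that plan. The alternatives were quantile normalization, median scaling, no filter, the upper part of genes by mean expression, no intensity trend, title style as a covariate, leaving out the CB6 pair or each library in turn, and other thresholds. Leaving out the 108 fill-in genes was added after seeing the data.

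The tests were checked on simulated data with the real genes' means for the comparison of knockdown with control. An effect of title style was added to each simulated gene and then removed with the group difference kept. This setting favours the fit with title style by construction. Of 12958 simulated genes, the fit without title style recovered 67 of 100 genes changed by 0.5 on the log2 scale and 91 of 100 changed by 1, with 37 false calls. With title style it recovered 47 and 82, with 9 false calls. When the podocyte list was shifted by -0.3, camera called it and 0 of 20 other lists. The simulated genes varied independently, while the estimated correlation of the real podocyte list was 0.625. The absence of false list calls in the simulation therefore does not carry over to the real lists.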

Results

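RNA was sequenced from isolated glomeruli, the filtering units of the kidney, of 7 male BALB/c mice aged 14 weeks. All mice received doxycycline in food and water for 6 weeks from the age of 8 weeks. The knockdown group (n = 3) carried an siRNA transgene directed at Shroom3, and the control group (n = 4) consisted of littermates without that transgene. Shroom3 encodes an actin-binding protein of cell junctions. The series title places the work in the context of Shroom3, the Src-family kinase Fyn, phosphorylation of the podocyte protein nephrin and albuminuria, so the comparison asks what glomeruli of knockdown mice express differently. Each library had a log2 expression value for 12958 gene symbols, with library medians between 9.15 and 9.16. Read counts were not used here, so sequencing depth and counting error are unknown. Sample titles came in 2 styles: 5 libraries had titles starting with G (2 knockdown, 3 control) and the other two had titles starting with CB6 (1 knockdown, 1 control).

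Shroom3 transcript was not detectably lower in the libraries labelled knockdown. Shroom3 (ENSMUSG00000029381.16; GRCm38 chromosome 5, 92683435 to 92965318, plus strand) had a mean log2 expression of 10.87 ± 0.06 (SD, n = 3) in knockdown and 11.05 ± 0.22 (SD, n = 4) in control glomeruli. The 3 knockdown libraries held 10.80, 10.91 and 10.89, and the 4 control libraries 10.94, 10.85, 11.36 and 11.06. The log2 fold change was -0.19 (SE 0.11, 95% CI -0.44 to 0.07) and did not pass the test (limma with Benjamini-Hochberg adjustment, adjusted p = 0.417). A two-sided exact permutation test gave p = 0.229, where the 35 possible splits of the 7 libraries allow no p below 0.0286. Shroom3 differed by -0.20 within the libraries titled G and by -0.17 within the CB6 pair. Without control replicate 3, the highest of the controls, the log2 fold change was -0.09. Because the targeted transcript did not check the labels, the groups are named as labelled throughout. Shroom4, of the same family, was at 12.21 ± 0.07 (SD, n = 3) against 12.35 ± 0.03 (SD, n = 4) and did not pass either (log2 fold change -0.13; limma, Benjamini-Hochberg adjusted p = 0.226).

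Fyn was lower in each knockdown library (10.25 to 10.42) than in any control library (10.56 to 11.04) but missed the threshold over all genes. Groups that did not overlap were common, at 2380 of the 12958 genes tested. Nphs1, the gene of nephrin, differed little against its spread. Fyn (chromosome 10, 39368855 to 39565381) had a mean log2 expression of 10.36 ± 0.10 (SD, n = 3) in knockdown and 10.85 ± 0.20 (SD, n = 4) in control glomeruli, a log2 fold change of -0.49 (SE 0.11). Its adjusted p lay just above the threshold (limma, Benjamini-Hochberg adjusted p = 0.0533), and the exact permutation p was 0.0571. Adjusted over the list of nephrin phosphorylation and Src-family signalling alone, Fyn passed (limma, Benjamini-Hochberg adjusted p = 0.0168). It also passed in 4 of 15 other settings, with adjusted p (limma, Benjamini-Hochberg) from 0.00861 to 0.344 over these settings. Over all genes it passed with quantile normalization (adjusted p = 0.0456) and without control replicate 2 (adjusted p = 0.00861). The others adjusted over fewer genes: the upper part of genes by mean (adjusted p = 0.0393) and without the fill-in genes (adjusted p = 0.0429), the latter added after seeing the data. Fyn differed by -0.51 within the libraries titled G and by -0.46 within the CB6 pair. Nphs1 (chromosome 7, 30458315 to 30487223) was at 12.47 ± 0.09 (SD, n = 3) and 12.58 ± 0.21 (SD, n = 4), a log2 fold change of -0.11 (limma, Benjamini-Hochberg adjusted p = 0.645; exact permutation p = 0.429). With a library left out Nphs1 ran from -0.20 (without control replicate 2) to -0.04 (without control replicate 3). These values concern transcript only, and nephrin phosphorylation was not analysed here.

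**Figure D1:**
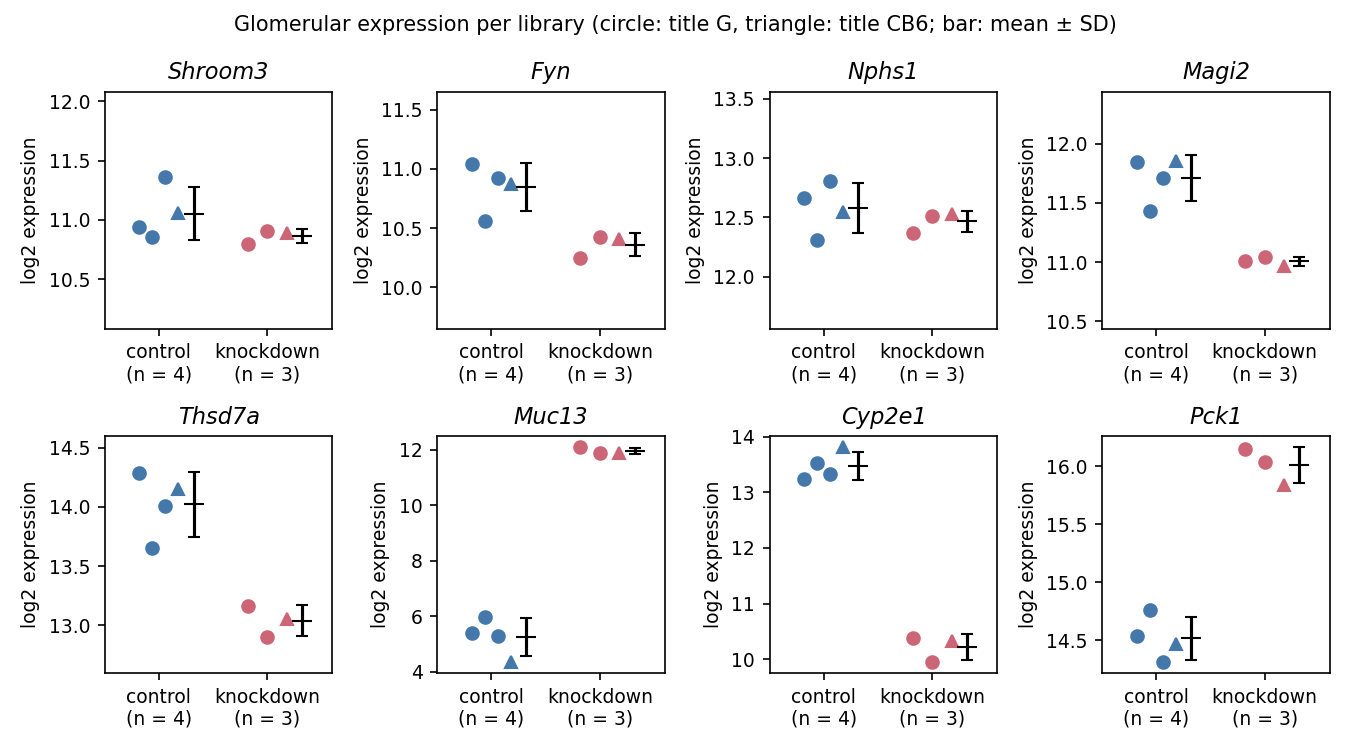
Log2 expression of 8 genes in each of the 7 libraries, control on the left (n = 4) and knockdown on the right (n = 3) of each panel; circles are libraries titled G, triangles libraries titled CB6, and the bar beside each group is its mean with SD. Shroom3 and Nphs1 overlapped between groups, while Muc13 and Pck1 were higher, and Cyp2e1, Magi2 and Thsd7a lower, in every knockdown library than in any control library.

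Muc13, which encodes a transmembrane mucin of epithelial surfaces, had the largest rise among the named genes. It went from a mean log2 expression of 5.26 ± 0.67 (SD, n = 4) in control to 11.96 ± 0.12 (SD, n = 3) in knockdown glomeruli, a 104-fold difference (log2 fold change 6.70, SE 0.32; limma, Benjamini-Hochberg adjusted p = 7.66e-05). Its control mean lay at the 1.49th percentile of all genes, close to the lowest values in the tables, and its knockdown mean at the 92.8th. Several genes of enzymes and carriers rose as well: Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, by 1.49 on the log2 scale, Ugt1a2, a glucuronosyltransferase, by 1.81, Gstm5, a glutathione transferase, by 2.17, Hao2, a peroxisomal hydroxyacid oxidase, by 1.85, and Scp2, a sterol carrier, by 1.25. Edn3, which encodes an endothelin peptide, rose by 2.26, Clic6 by 2.12 and the transcription factor Maf by 1.06. The endosomal tether Eea1 rose by 1.01, Nt5c2 by 0.70, Ppat of purine synthesis by 0.64, Pcyox1 by 0.50 and the ethanolamine kinase Etnk1 by 0.47, while Ldlrad4 rose from a mean of 9.78 to 10.78. Exons shared between the Ugt1a genes make reads hard to assign to Ugt1a2 alone.

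The genes that fell included transporters and enzymes of tubule cells. Slco1a1, an organic anion transporter, fell from 10.37 ± 0.52 (SD, n = 4) to 6.22 ± 0.56 (SD, n = 3), a log2 fold change of -4.15 (SE 0.32). Cyp2e1, a cytochrome P450, fell from 13.48 ± 0.25 (SD, n = 4) to 10.22 ± 0.24 (SD, n = 3), a log2 fold change of -3.26 (SE 0.15; limma, Benjamini-Hochberg adjusted p = 7.66e-05). The carboxylesterases Ces1f and Ces2c had log2 fold changes of -3.03 and -1.41, the urate transporter Slc22a12 of -2.26, the nuclease Dnase1 of -2.06 and the dipeptidase Cndp2 of -1.98. The secreted factors Fgfbp1 and Angptl7 had log2 fold changes of -2.72 and -2.71, the chemokine Cxcl13 of -1.71 and the fatty acid receptor Cd36 of -1.39. Aspg changed by -1.59, the antiplasmin gene Serpinf2 by -1.58, the lymphocyte phosphatase Ptpn22 by -1.26 and the synapsin Syn3 by -0.90. Members of the carboxylesterase and Slco1a families resemble each other in sequence, so how reads were shared among them is uncertain.

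**Figure D2:**
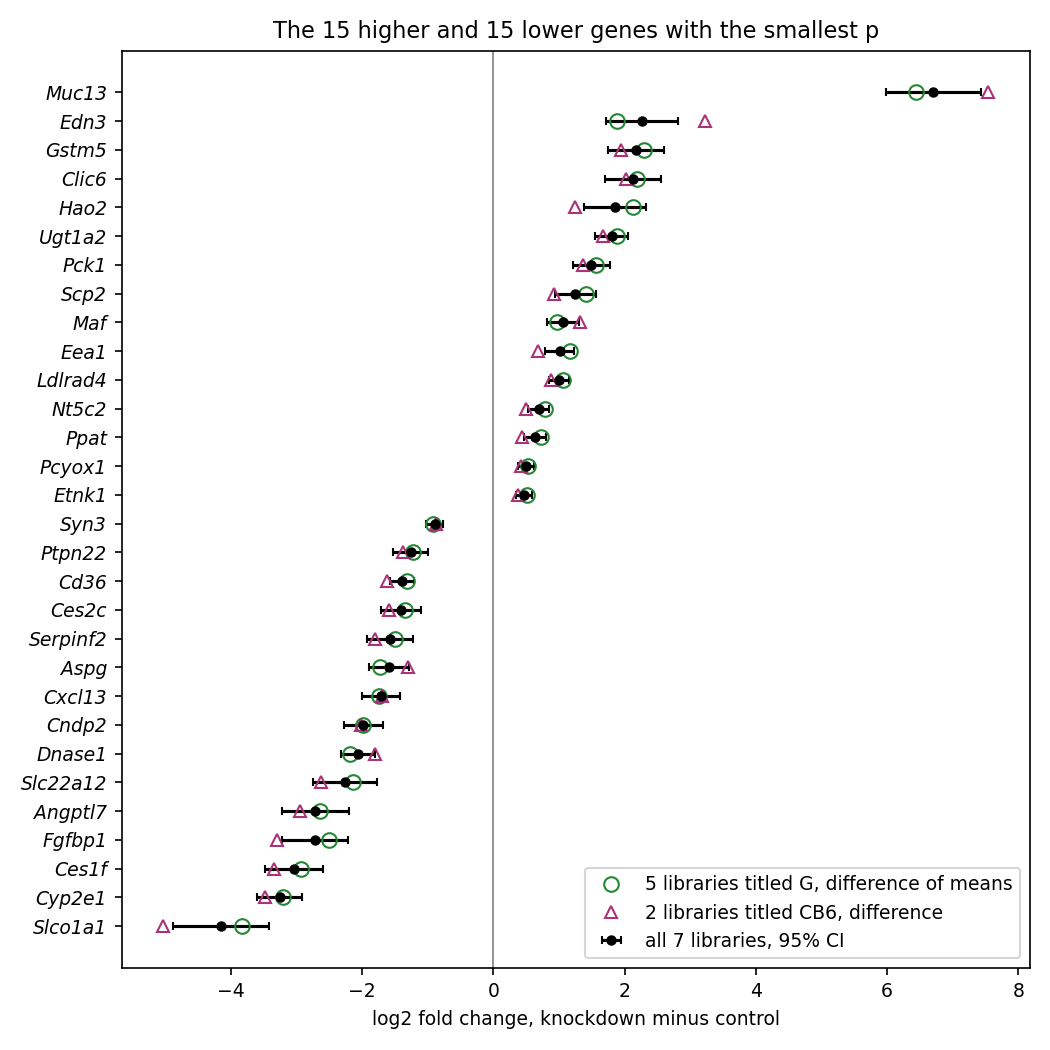
Log2 fold change (knockdown minus control) of the 15 higher and 15 lower genes with the smallest p, with 95% CI over all 7 libraries (black), the difference of means within the 5 libraries titled G (green circles) and the difference within the 2 libraries titled CB6 (purple triangles). Over all 7 libraries the log2 fold changes ran from -4.15 for Slco1a1 to 6.70 for Muc13; the genes were chosen by p over the same libraries, which favours the same direction in both title styles.

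Over all genes, 391 of 12958 passed an adjusted p of 0.05 (3.02%; limma with Benjamini-Hochberg adjustment), 129 higher and 262 lower in knockdown. Of these, 93 changed by at least 1 on the log2 scale, 19 higher and 74 lower. For each of the 391 genes, all knockdown libraries lay on the same side of all control libraries, which choosing them by this difference favours. The same held for 2380 of the 12958 genes tested. Chance gives 5.71% of genes if all splits are equally likely, which an adjustment before deposit that kept the group difference would not leave so. Title style as a covariate left 191 of the 391 genes (44 higher, 147 lower), and the 5 libraries titled G alone gave 40 genes (14 higher, 26 lower), of which 37 were among the 391. The count was 203, 134 and 147 without knockdown replicates 1, 2 and 3 in turn, and 146 without control replicate 4. Of the 47 named genes past the threshold, 36 remained past it with title style as a covariate and 24 in the libraries titled G alone. Without knockdown replicates 1, 2 and 3 in turn 34, 32 and 34 remained, and without control replicates 1 to 4 in turn 38, 44, 38 and 33. The log2 fold changes of the 11 named genes lost with title style moved by at most 0.0083, so these calls ended through larger p-values, not smaller differences. The coefficient of the CB6 pair was small across genes (SD 0.0283). The folds could therefore hardly move, and this does not show that they are free of an effect of title style.

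Podocyte markers were lower as a group. Of 31 measured markers of these filtration barrier cells, 27 had a negative log2 fold change, with a median of -0.29, and 4 fell: Thsd7a (-0.98), Magi2 (-0.70), a scaffold protein of the slit diaphragm, Col4a3 (-0.63), a collagen chain of the glomerular basement membrane, and Vegfa (-0.51). None rose, and 15 were lower when adjusted over the list alone. The list was lower than other genes by limma's camera with a preset correlation (Benjamini-Hochberg adjusted p = 7.36e-09), with an adjusted p = 0.643 with an estimated correlation. The mean over the list was 12.26 ± 0.08 (SD, n = 3) in knockdown and 12.55 ± 0.19 (SD, n = 4) in control libraries (exact permutation p = 0.0857). With title style as a covariate, Vegfa (-0.51) and Col4a3 (-0.64) no longer passed at nearly unmoved log2 fold changes, and none of the 4 passed in the libraries titled G alone. Proximal tubule markers were lower in the same libraries, with a median log2 fold change of -0.35.

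Endothelial and mesangial markers had mostly negative log2 fold changes. Of 24 glomerular endothelial markers, 20 had a negative log2 fold change (median -0.21) and none passed singly or adjusted over the list alone. The most highly expressed of them, Plat, the tissue plasminogen activator, and Ehd3, differed by -0.09 and -0.23. Of 15 mesangial markers, 12 were negative (median -0.14), and Sfrp2 (-0.98), a secreted Wnt modulator, and Serpine2 (-0.39), a protease inhibitor, fell, 2 also when adjusted over the list alone. Neither Sfrp2 nor Serpine2 passed with title style as a covariate or in the libraries titled G alone. By limma's camera with Benjamini-Hochberg adjustment the endothelial list had an adjusted p = 4.48e-05 and the mesangial list an adjusted p = 0.0119, each with an adjusted p = 0.643 with an estimated correlation. Exact permutation tests of the mean over each list gave p = 0.2 for both. The mesangial list did not pass without knockdown replicate 1, control replicate 1 or control replicate 3 (medians -0.04, -0.11 and -0.03), and the endothelial median was -0.14 without control replicate 1.

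Among the gene groups tied to the study's question, single genes passed. Over all genes 3.02% passed, and whether these groups held more than that share was not tested. In the list of nephrin phosphorylation and Src-family signalling, Cblb, a ubiquitin ligase, fell (-0.39) among 29 measured genes, with 4 lower when adjusted over the list alone, Fyn among them. Of 42 genes of actin filament binding and assembly, Enah, which promotes filament elongation, rose (0.22), and 0 passed adjusted over the list alone. The 27 focal adhesion and integrin genes included none past the threshold, also adjusted over the list alone, and Tns1 and Itgb1 differed by 0.14 and 0.01, the latter turning to -0.0051 under quantile normalization. As a group these 27 genes had a median of -0.07. The mean over the list was 11.65 ± 0.10 (SD, n = 3) in knockdown and 11.74 ± 0.13 (SD, n = 4) in control libraries (exact permutation p = 0.343). The list was lower by limma's camera (Benjamini-Hochberg adjusted p = 0.0276), with an adjusted p = 0.643 with an estimated correlation. This list did not pass without knockdown replicate 1, control replicate 1 or control replicate 3 (medians -0.03, -0.09 and -0.02), and its median was -0.13 without knockdown replicate 2 and -0.12 without control replicate 2. The nephrin and actin lists did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.0511 and 0.0613), nor did the 4 genes of the Shroom family (adjusted p = 0.387, 0 genes past the threshold singly or adjusted over the list alone). Cblb and Enah did not pass with title style as a covariate or in the libraries titled G alone.

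Among cells outside the tuft, the proximal tubule had the most markers past the threshold. Of 26 proximal tubule markers 9 fell, among them Cyp2e1, Slc22a12 (-2.26) and Cyp4b1 (-1.06), and Pck1 rose. Adjusted over the list alone, 12 were lower and 2 higher. The list was lower by limma's camera (Benjamini-Hochberg adjusted p = 8.79e-08; adjusted p = 0.643 with an estimated correlation), and its mean was 12.57 ± 0.21 (SD, n = 3) against 13.13 ± 0.13 (SD, n = 4), with an exact permutation p of 0.0286, the smallest possible. With title style as a covariate 7 of its members were lower and 1 higher. Slc4a1 (0.86), the anion exchanger, and Atp6v1g3 (0.56), a proton pump subunit, both of acid-base transporting cells of the collecting duct, rose among 18 distal nephron and collecting duct markers, 3 when adjusted over the list alone. That list did not pass camera (median 0.21; limma, Benjamini-Hochberg adjusted p = 0.0919), and Atp6v1g3 did not pass with title style as a covariate. No smooth muscle and renin cell marker of 9, parietal epithelial marker of 8 or immune cell marker of 11 passed, also adjusted over each list alone. Their medians were 0.13, 0.08 and 0.10, with camera adjusted p of 0.515, 0.744 and 0.584 (limma, Benjamini-Hochberg). The parietal list had a mean of -0.03 and a downward camera direction, opposite to its median. Among these lists Myh11 and Acta2 differed by 0.30 and 0.24, Pax8 and Scin by 0.12 and -0.13, and Ptprc by -0.26, while Csf1r was at 9.25 ± 0.03 (SD, n = 3) and 9.24 ± 0.09 (SD, n = 4). Of 2 measured red cell markers, too few for a list test, Alas2, the erythroid heme synthesis enzyme, fell (-0.54), also adjusted over the list alone, but did not pass with title style as a covariate.

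**Figure D3:**
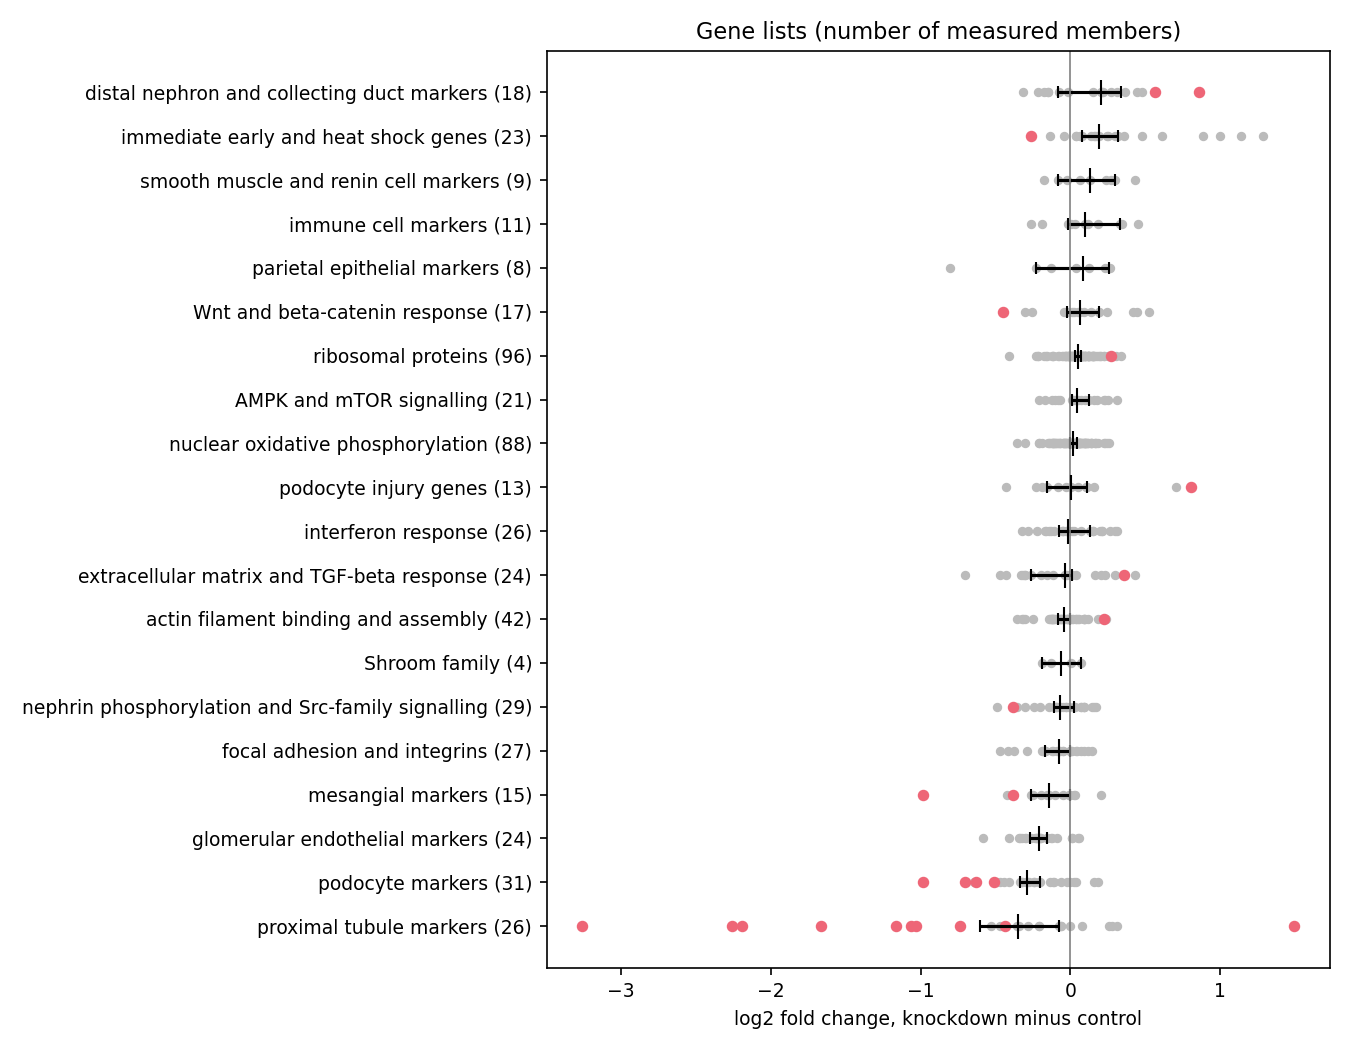
Log2 fold change (knockdown minus control) of every measured member of 20 of the gene lists; red points passed an adjusted p of 0.05 over all genes, grey points did not, and the black mark and bar are the list's median with its 95% bootstrap interval over genes. Proximal tubule, podocyte and endothelial markers had the lowest medians, -0.35, -0.29 and -0.21.

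Of 23 immediate early and heat shock genes, 20 were positive, with a median of 0.19. The mean over the list was 9.52 ± 0.18 (SD, n = 3) in knockdown and 9.20 ± 0.16 (SD, n = 4) in control libraries (exact permutation p = 0.143). The list was higher by limma's camera (Benjamini-Hochberg adjusted p = 0.0139), with an adjusted p = 0.643 with an estimated correlation. The list did not pass without knockdown replicate 2 or control replicate 2 (medians 0.16 and 0.15). The single member past the threshold, the transcription factor Klf6, fell (-0.26), against the direction of its list, and did not pass with title style as a covariate. Adjusted over the list alone, 1 gene was higher and 1 lower. Among 24 genes of extracellular matrix and TGF-beta response, the receptor Tgfbr1 rose (0.36), with 3 higher and 7 lower when adjusted over the list alone. Among 17 Wnt and beta-catenin response genes, the cyclin Ccnd1 fell (-0.45), with 1 higher and 1 lower adjusted over the list alone. Spp1, which encodes osteopontin, rose (0.81) among 13 podocyte injury genes, 1 also adjusted over the list alone, and Rps4x rose (0.27) among 96 ribosomal protein genes, 0 adjusted over the list alone. Spp1 and Rps4x did not pass with title style as a covariate. None of 26 interferon response, 21 AMPK and mTOR or 88 nuclear oxidative phosphorylation genes passed, also adjusted over each list alone. Ddx58 differed by 0.21, Mtor by 0.16 and Prkaa2 by 0.01, while Atp5a1 and Atp5b differed by 0.05 and -0.01. None of these lists but the immediate early one passed camera, the smallest of the other adjusted p being 0.0511 for ribosomal proteins (limma, Benjamini-Hochberg). The interferon list had a median of -0.02 and a mean of 0.01 with an upward camera direction.

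In all, 6 of 21 lists passed limma's camera, 5 lower and 1 higher, and 26 of 563 list genes passed singly, 13 of them with title style as a covariate. Over all genes 3.02% passed, and of the 26 list genes 9 lower and 1 higher were proximal tubule markers. In the libraries titled G alone 3 list genes passed, Cyp2e1, Slc22a12 and Pck1, so that Slc4a1, Tgfbr1 and Ccnd1, among others, did not. With an estimated correlation 0 lists passed (0 at an unadjusted p under 0.05), and by fry, which asks whether a list's genes move on balance in 1 direction, 0 passed (1 at an unadjusted p under 0.05). In the libraries titled G alone the same 6 lists passed camera. The number of lists was 10 without knockdown replicate 2 and also 10 without control replicate 2, and without control replicate 1 it was 4. The number of list genes was 13, 7 and 10 without knockdown replicates 1, 2 and 3 in turn, and 48 and 10 without control replicates 2 and 4.

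Genes past the threshold were not gathered on a chromosome. In Fisher's exact test 0 of 20 chromosomes passed (0 at an unadjusted p under 0.05), the smallest adjusted p being 0.449. The lowest unadjusted p, 0.0572, was that of chromosome 11, with 21 of 1032 genes. Chromosome 5, which carries Shroom3, had 33 of 804 and chromosome 16, which carries Muc13, 16 of 406. Without knockdown replicate 3 the number of chromosomes past the threshold was 1.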

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

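The rule used here was set before the data were examined, and no test was chosen afterwards. Among the 69 named genes, control libraries set apart from the others were found for Aspg alone. Control replicate 2 held a log2 expression of 7.55 against 7.35, 7.37 and 7.38 in the other controls, a gap of 0.853 of the group's range, above Dixon's 95% critical value for 4 samples. Chance sets apart about 1 in 20 such groups. The knockdown libraries, at 5.61, 5.77 and 6.08, lay below all controls whether or not that library was counted.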

How the results depend on the processing

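Leaving out the 108 fill-in genes (432 genes past the threshold) and the other settings of the chromosome test, itself planned, were chosen after seeing the data, and so was the use of a list's median for its direction. The count of 391 genes became 191 with title style as a covariate, 40 without the CB6 pair, 846 at an adjusted p under 0.1, 93 with a log2 fold change of at least 1, and 134 to 480 with each library left out in turn. It was 434 with quantile normalization, 378 with median scaling, 314 without the trend and 309 in the upper part of genes by mean. Leaving out the filter changed nothing because it removed nothing. The 26 list genes became 16 without the trend, 13 with title style, 3 without the CB6 pair, 52 at the looser threshold, 8 with the fold limit and 7 to 48 with a library left out. The 6 lists became 11 in the upper part of genes, 12 at the looser threshold, 0 with an estimated correlation, 0 by fry and 4 to 10 with a library left out. Chromosomes past the threshold were 0 to 1 with a library left out. A looser threshold raises a count and a fold limit lowers it by construction. Title style takes a residual degree of freedom and left the folds nearly unmoved. For the other changes, which went both ways with a library left out, the cause was not tested.

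The Shroom3 log2 fold change stayed negative and past no threshold in every setting. Of the 47 named genes past the threshold 0 reversed, and 32 to 44 remained past it with a library left out. Of the 6 lists, 4 to 6 remained, and 0 changed direction. Directions reversed only for values past no threshold. Itgb1 was at -0.0051 under quantile normalization and ran from -0.038 to 0.052 with a library left out. Csf1r was at -0.0026 under median scaling, -0.021 without the CB6 pair and -0.036 to 0.031 with a library left out. Atp5b was at 0.017 under quantile normalization and -0.048 to 0.040 with a library left out. With a library left out, Plat ran from -0.22 to 0.081, Prkaa2 from -0.067 to 0.083 and Atp5a1 from -0.0071 to 0.097. List medians that reversed were smooth muscle (-0.060 without the CB6 pair), parietal (-0.069 without that pair, -0.076 to 0.18 with a library left out), interferon (-0.036 to 0.085), oxidative phosphorylation (-0.0094 to 0.057) and podocyte injury (-7.93e-05 under median scaling). The cause was not tested.

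Tests for counts (edgeR, DESeq2, voom), other pseudocounts and the fold limit for lists were not run, because the values are logs and lists have no fold limit. No paired analysis was possible because the labels give the groups no shared replicate numbers. Depth is unknown, so what it limits could not be judged.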

Other observations

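The tests of gene families, of the female-biased list with added genes, of fewer proximal tubule cells, of female animals, of the batch adjustment and of a lower glomerular share were chosen after the results were seen. The families were symbol prefixes picked by hand, including those of leading genes such as Ces1f, Slco1a1 and Slc22a12. Fisher's exact test also treats related members as independent, so its p-values here do not show enrichment. Among 28 gene families tested in this way, 8 passed, and the carboxylesterases had the smallest p. Of 8 measured Ces genes 6 fell (Benjamini-Hochberg adjusted p = 5.41e-07), with Ces1f at -3.03, Ces1e at -1.61 and Ces1d at -1.09. Of 20 Slc22a organic ion transporters 5 fell (adjusted p = 0.00243), among them Slc22a30 (-2.29) and Slc22a6 (-1.17), and of 7 Slco transporters 3 fell (adjusted p = 0.0061). Of 8 Ugt1 genes 4 rose (adjusted p = 0.000727), but these share exons and so reads. The other families that passed were Slc5a (2 of 11 rose and 1 fell, adjusted p = 0.0181), Cyp2 (1 of 22 rose and 3 fell, adjusted p = 0.0181), Slc16a (3 of 13 fell, adjusted p = 0.0249) and Slc1a (2 of 5 fell, adjusted p = 0.0299). The numbers were the same under quantile normalization and median scaling for all 8, but with title style as a covariate 4 Ces, 4 Slc22a, 2 Slco and 1 Ugt1 genes passed, and without the CB6 pair 1, 2, 1 and 1. Single libraries moved the numbers too: 3 Ces genes passed without knockdown replicate 1, 2 or 3 or control replicate 4, and 2 Slc22a genes without knockdown replicate 2. For Ugt1 it was 2 without knockdown replicate 1, 1 without knockdown replicate 2 or 3 or control replicate 4, and 7 without control replicate 2. With title style, 1 Slc5a gene rose, 1 Cyp2 gene rose and 2 fell, and 3 Slc16a and 1 Slc1a genes fell, while without the CB6 pair 2 Cyp2 genes fell and 0 genes of the other three families passed. No Slc5a gene passed without knockdown replicate 2, and no Slc1a gene without knockdown replicate 3 or control replicate 4. Other large falls, picked after their values were seen, were those of Ugt2b38 (-4.07), the amine methyltransferase Inmt (-3.21), the chemokine Ccl28 (-3.20) and the RNA sensor Tlr7 (-3.01).

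Muc13 stood alone in its region: of 13 tested genes within 1 Mb on chromosome 16 (Muc13 at 33794037 to 33819934), 0 passed the threshold, and the largest absolute log2 fold change among them was 0.42.

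Genes known to be higher in male than in female mouse kidney were lower in the libraries labelled knockdown, a hypothesis from the leading genes, of which 14 on the list had been seen to fall. For 7 further male-biased genes (of 9 listed from background knowledge, with no reference table, before their values were looked at, 1 not measured and 1 at the fill-in value), the median log2 fold change was -0.96, below each of 10000 random lists matched on mean expression (95% of them from -0.12 to 0.14). Of these, Slc22a6 (-1.17), Adh1 (-1.04), Acsm3 (-1.02), Gusb (-0.96) and Odc1 (-0.84) fell, while Cyp7b1 (-0.34) and Cyp4a12a (0.05) did not pass. In contrast, 7 female-biased genes had a median of 0.37 with 0 past the threshold. Of them 6 were positive, while Slc22a7 (-0.78) went against the pattern. The median was 0.30 with Cyp2a4 (-2.16) and Cyp2d12 (-2.85) added. These had been seen to fall and were left off both lists because their sex bias was uncertain. Fewer proximal tubule cells as the whole cause are argued against, since all 26 proximal tubule markers, 6 of them on the male-biased list, had a median of -0.35 (bootstrap interval -0.61 to -0.07), above -0.96, and so are female animals, since the lowest knockdown library lay at -0.044 from the control mean over 3 Y-linked genes. The random lists were drawn from all genes, so they cannot tell a fall of male-biased genes from another change shared by tubule genes. Slc22a6 is also on the proximal tubule list, so its fall is not independent of that list. A lower androgen response of tubule cells may account for the pattern but was not told apart from such a change. Whether the pattern came with the transgene or from differences between individual males, whose hormones were not analysed here, stays open.

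The libraries titled CB6 deviated from their groups in opposite ways across genes. The coefficient of this pair, fitted as a term beside the groups, had an SD over genes of 0.0283, against 0.143 to 0.203 for the 11 other pairs of a knockdown and a control library. This is consistent with an adjustment for title style, made before deposit, that kept the group difference. If so, the 391 genes rest on more degrees of freedom than the data held, and the count of 191 with title style is the fairer one. Of the 35 splits of the 7 libraries, 1, the real one, gave as many as 391 genes, and the highest other gave 12, so chance is excluded only as far as that adjustment did not itself favour the real groups.

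Podocyte, endothelial and mesangial markers had medians of -0.29, -0.21 and -0.14, the last -0.03 without control replicate 3 and -0.04 without knockdown replicate 1, and the endothelial one -0.14 without control replicate 1. Chance cannot be excluded for the lists: 22 of the 35 splits gave at least the 6 lists of the real groups, and the highest other gave 14. A lower share of glomerular RNA cannot be told apart from a change within these cells, because the distal nephron (0.21), smooth muscle (0.13), immune (0.10) and parietal markers (0.082, the lowest) had positive medians, as a lower share needs, but with bootstrap intervals that included 0. With a library left out these medians ran, in that order, from 0.12 to 0.25, 0.019 to 0.23, 0.030 to 0.15 and -0.076 to 0.18. Proximal tubule markers were lower (-0.35) where a lower share needs a rise. Of these 26 markers 6 are on the male-biased list. Off that list, Acsm2 (-1.03), Slc13a3 (-0.74) and Slc5a2 (-0.44) also fell, while Pck1 (1.49) rose. The markers off that list were not tested as a set, so the proximal tubule does not decide. Podocyte minus endothelial markers differed by -0.07 between groups (exact permutation p = 0.229), podocyte minus mesangial by -0.11 (p = 0.0857) and endothelial minus mesangial by -0.04 (p = 0.0286, the smallest possible), so a fall specific to podocytes was not detected.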
